A study of Danio rerio with 16 samples.

How the data were processed

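RNA of 16 muscle pools was labelled with Cy3 and hybridised to Agilent 4x44K zebrafish arrays, per the labels' protocols, from 50 ng of RNA per labelling and 1650 ng of labelled cRNA per array. Per the file headers, the scanner intensity values were read by Agilent Feature Extraction 10.7.3.1, which subtracts background and corrects spatial trends within an array, with no scaling between arrays. The log2 values that the authors deposited in the series table are not accompanied by a statement of their steps. These values ran with the processed intensity of the same spots at Spearman correlations of 0.9981 to 0.9994, had medians of 8.28 to 8.41 per array, and were empty at exactly the spots not well above background (100% of spots).

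The main analysis took log2 of the processed intensity minus the array's 75th percentile over 43803 non-control spots. Spots with outlier marks were left out and replicate spots averaged. Probes well above background on at least 4 of 16 arrays were kept (37861 of 43603), and the probe with the highest mean over all arrays stood for its gene, which gave 24216 genes. Names came from RefSeq accessions matched to the reference table of GRCz12tu (12848 of 13645 accessions), so 11953 genes (49.4%) had a symbol. The array grid uses the older danRer6 build, and no coordinates were used. The 75th percentile of the intensity ranged from 411.1 to 742.6. Control flow was taken from the source description, which gives 0 cm/s, although the control titles speak of low flow.

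Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 12 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment at 0.05. The 7 contrasts were the 6 pairs of groups and the interaction. Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, over 24098 genes without missing values. Camera compares a list with the other genes, while fry tests whether the genes of a list move one way on balance, against no movement. The 30 lists covered metabolism, contractile genes, protein turnover, translation, stress, growth, matrix and cell type markers. The contrasts, the lists, the rule for naming genes and the other settings listed next were chosen before the data were examined. The rule named the up to 8 genes per direction with the largest change past the threshold and no overlap of groups for contrasts with control, and 5 otherwise, filled to 5 by the smallest p, with up to 4 examples per list and 17 single genes. Items without an informative symbol were outside the rule. The steps were tested on simulated data with known changes.

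Lists of oocyte, testis, liver and kidney markers were written after the first principal component had been seen, and these tests are exploratory. The other settings fixed beforehand were quantile normalisation, the array median, the authors' values, no filter and a stricter filter, the mean of probes, slide and replicate number as blocks, no variance trend, array quality weights, only the groups compared, and each array left out in turn. A planned background correction (normexp) needed a mean signal column that was not used here, and the median signal with an offset of 50 took its place after the data were seen. Also chosen after seeing the data were the oocyte marker mean, alone or with the liver marker mean, as covariates, and subsets of 12 and 14 arrays. Overlap was set against unchanged groups drawn from the residuals of all arrays, with a drawn group as the shared reference in place of the controls. No array was left out of the main analysis and no label was changed.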

Results

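Transcript levels were measured in the post-anal skeletal muscle of zebrafish on 16 single-colour oligonucleotide arrays, each hybridised with pooled RNA of 2 to 3 fish. The fish were 4 months old, of mixed sex, and spent 5 days under test conditions. The normoxia_control group was kept at 20 kPa oxygen without imposed flow. The normoxia_exercise group swam at 35 cm/s for 6 h in every 24 h at 20 kPa. The hypoxia_exercise group swam at 30 cm/s for 6 h in every 24 h at 6 kPa, and the hypoxia_low_flow group was kept at 4 kPa with a flow of 7 cm/s. Each group had 4 arrays, and each of 4 slides carried 1 array of every group. Oxygen and speed differed in level between the hypoxic arms, so these arms are not matched in dose. Between 80.1% and 85.5% of probes lay well above background on each array, no spot was saturated, and the number of arrays limits the precision. Fold changes are log2 differences ± standard error between 4 and 4 arrays, and adjusted p values are from limma over 24216 genes.

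The arrays of a group were not alike in the transcripts of egg cells. The mean of 44 oocyte markers, relative to the mean of all arrays, was 5.90, 4.07, 5.45 and -2.44 in normoxia_control replicates 1 to 4. It was 0.87, -2.57, -2.48 and -2.46 in normoxia_exercise, -0.50, -2.63, -2.08 and 0.026 in hypoxia_exercise, and -2.66, -2.45, -2.33 and 6.41 in hypoxia_low_flow. The egg coat gene zp2.3 reached 8.06 on hypoxia_low_flow replicate 4 and 7.60 on normoxia_control replicate 1, where it exceeded 99.5% and 99.3% of genes, against -6.14 on normoxia_control replicate 4. The mean of 16 liver markers was 4.77 on hypoxia_exercise replicate 1 and at most 0.47 elsewhere. Leaving out hypoxia_low_flow replicate 4 or normoxia_control replicate 4 therefore lines oocyte content up more closely with the groups, which bears on each value given without either array. These marker lists were written after the first principal component had been seen. Exact two-sided permutation tests of 4 marker lists in 6 comparisons cannot give a p below 0.0286, so a lone difference cannot pass the adjustment over 24 tests, and the adjusted p values (0.457 at the lowest) do not show that the groups were alike. Replicates of a group correlated at 0.895 to 0.982 across genes, which are not independent replicates. The first principal component held 47.6% of the variance and set apart the arrays highest in oocyte markers. It lay at -149.6 to -84.3 on normoxia_control replicates 1 to 3 and hypoxia_low_flow replicate 4, and at -11.3 to 59.4 on the other arrays.

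**Figure D1:**
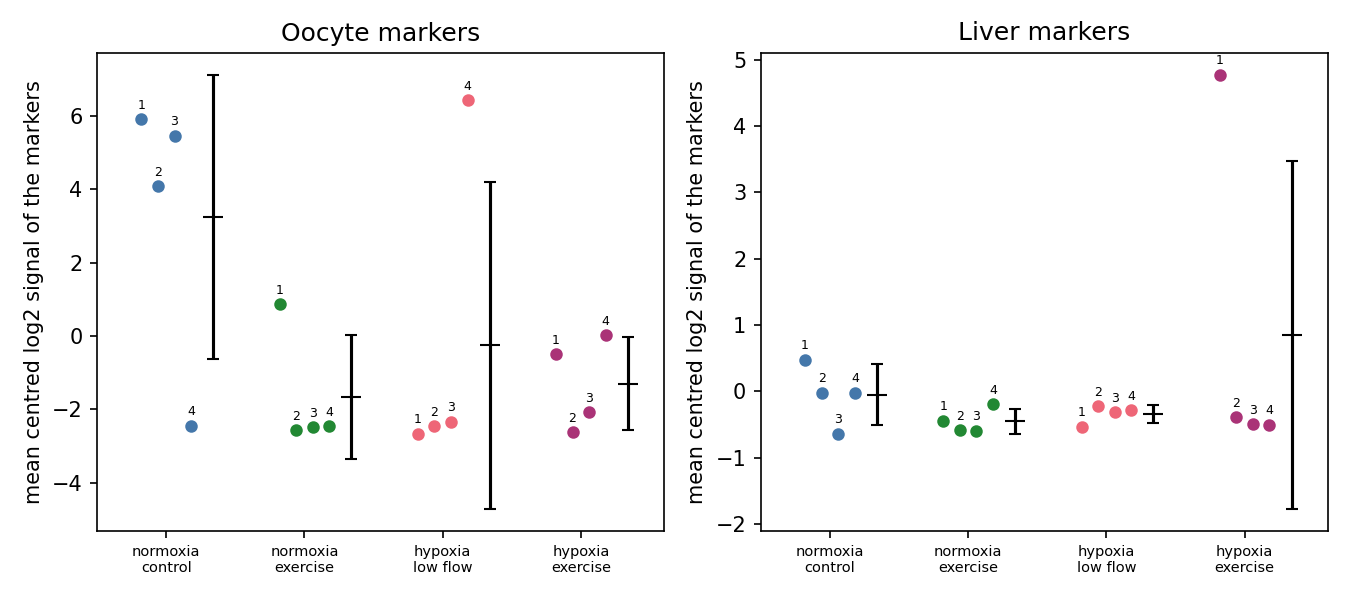
Mean centred log2 signal of 44 oocyte markers (left) and 16 liver markers (right) on each array, with the replicate number beside each point and the group mean ± SD in black (n = 4). Normoxia_control replicates 1 to 3 and hypoxia_low_flow replicate 4 lie at 4.07 to 6.41 in oocyte markers, and hypoxia_exercise replicate 1 lies at 4.77 in liver markers.

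The comparison of normoxia_exercise with normoxia_control asked what swimming changes in muscle at normal oxygen. The troponin I gene tnni4a rose by 1.81 ± 0.20 (adjusted p = 0.00541), the beta globin gene hbbe3 by 3.47 ± 0.48 (adjusted p = 0.0178) and the cytochrome c oxidase subunit gene cox6b1 by 1.90 ± 0.27 (adjusted p = 0.0201). The follistatin-like gene fstl1a rose by 2.00 ± 0.29 (adjusted p = 0.0201) and the nudix hydrolase gene nudt8 by 1.25 ± 0.16 (adjusted p = 0.0147). For all 5 genes the groups did not overlap, which the rule that named them required, and which chance gives a gene, in either direction, with a share of 0.0286. By construction, these genes were therefore also higher in exercise on 4 of 4 slides. Their identifiers on the array are NM_001005998 (tnni4a), NM_001015058 (hbbe3), NM_001002695 (cox6b1), NM_001017860 (fstl1a) and NM_001077316 (nudt8). With the transcripts AY329628 and ENSDART00000136543, which carry no symbol and were named after their values were seen, 7 genes rose and 0 fell by limma. AY329628 ran close to hbbe3 on each array (-4.79 and -4.51 on normoxia_control replicate 1, -1.87 and -1.72 on normoxia_exercise replicate 1), so they may not be separate signals. An unadjusted p under 0.05 was found for 2612 genes, where 1211 are expected on average by chance. That average gives no spread, and the excess was not parted from oocyte content. No gene that was lower passed the threshold, and the smallest unadjusted p values among them belonged to spag6 (-1.47 ± 0.33, adjusted p = 0.282), hs3st3b1a, cfap161, aif1l and chrna11, of which spag6 is also a testis marker and chrna11 turned higher by 0.071 under normexp background correction. Leaving out normoxia_control replicate 3 gave 10 genes, to which ENSDART00000136543 no longer belonged. Leaving out normoxia_control replicate 1, 2 or 4 left 3, 1 and 3 genes, and leaving out normoxia_exercise replicate 1, 3 or 4 left 1, 1 and 2, with tnni4a past the threshold each time (largest adjusted p = 0.0419). With slide as a term in the model 5 genes passed, with array quality weights 58 (41 higher and 17 lower), with the authors' values 12 (10 higher and 2 lower), and with normexp or with the oocyte marker mean as a covariate 0. The adjusted p of tnni4a ranged from 0.000319 to 0.388 over all settings. In data simulated for this comparison on 24098 genes, 4%, 30%, 80% and 94% of genes changed by 0.5, 1, 2 and 3 log2 units were recovered, and of 112 calls 6 were false and 2 came from a list of 40 genes shifted by 0.5. The simulated noise was independent between genes, whereas genes moved together on the real arrays, so these shares may not hold for them. The oocyte marker mean was lower in normoxia_exercise by -4.91 (exact permutation p = 0.0571).

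**Figure D2:**
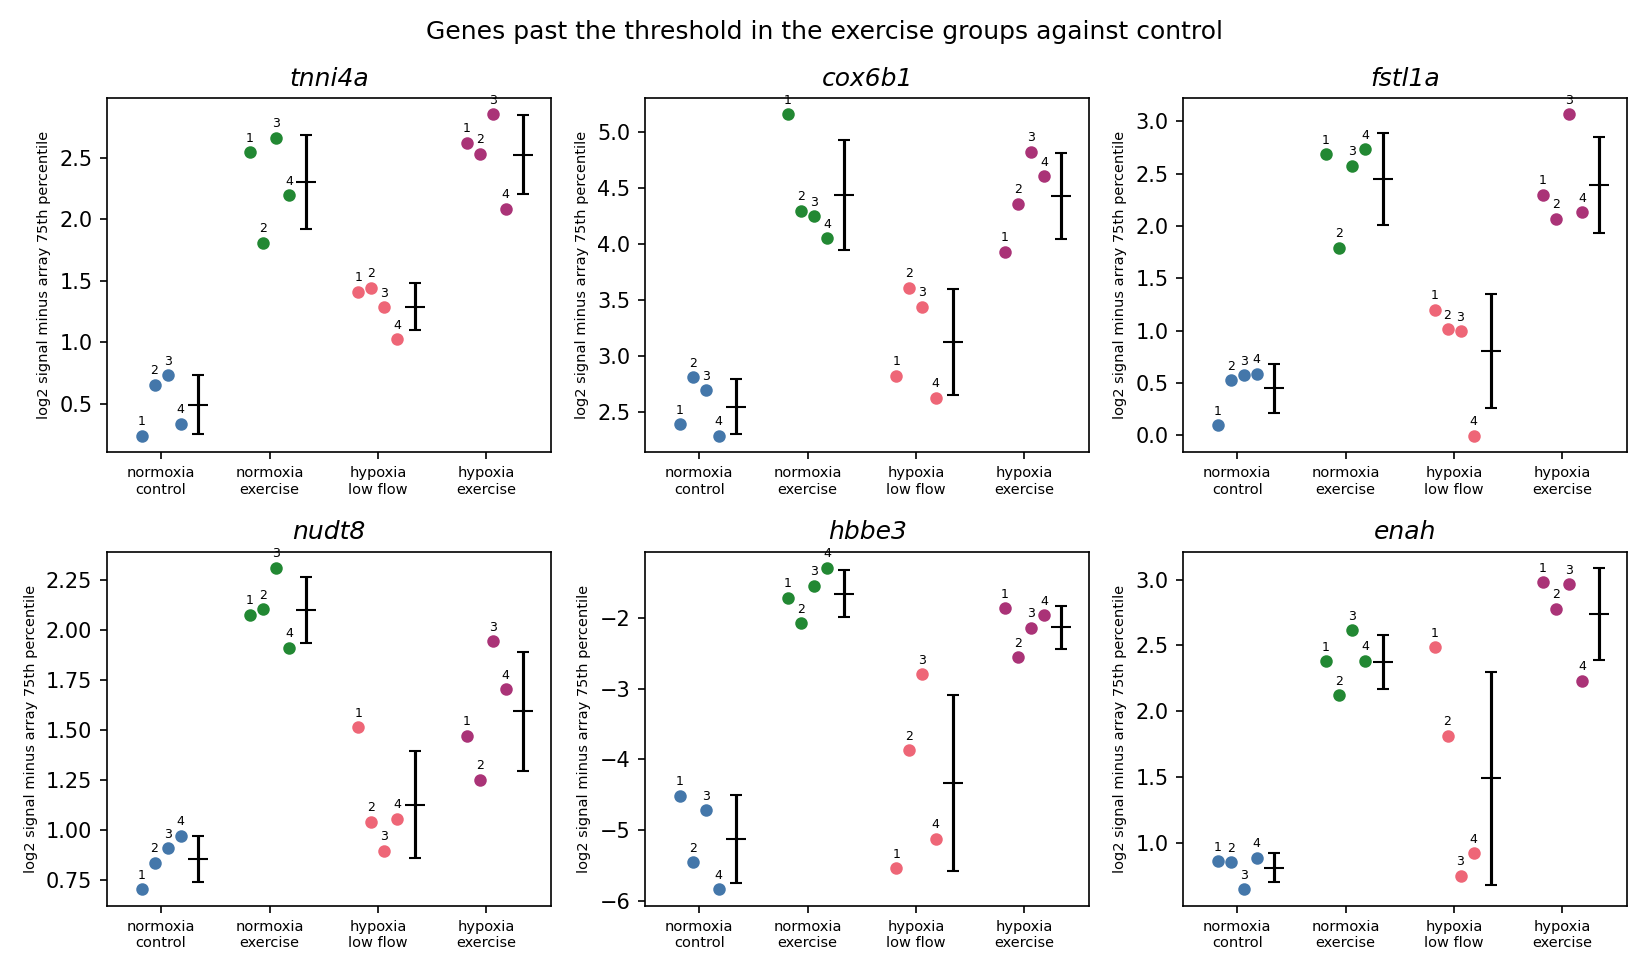
Log2 signal relative to the array's 75th percentile of 6 genes past the threshold in normoxia_exercise or hypoxia_exercise against normoxia_control, per array with its replicate number and with group mean ± SD in black (n = 4). The level of fstl1a was 0.45 ± 0.24 in normoxia_control, 2.44 ± 0.44 in normoxia_exercise and 2.39 ± 0.46 in hypoxia_exercise.

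Among gene lists fixed before the data were examined, 16 of 30 passed in normoxia_exercise by camera with a preset correlation, none of which held with an estimated correlation (smallest adjusted p = 0.704). Fatty acid uptake and oxidation lay 0.51 above the mean of the other genes (30 of 33 members higher, 4 of 4 slides, adjusted p = 6.99e-09), and 11 of its members passed when adjusted over the list alone, among them acadvl (1.01 ± 0.17), etfb (0.61 ± 0.16), fabp3 and etfdh. Proteasome subunits lay 0.50 higher (42 of 43 members, adjusted p = 6.7e-12). Oxidative phosphorylation lay 0.35 higher (66 of 68 members, adjusted p = 4.36e-08) and the tricarboxylic acid cycle 0.29 higher (20 of 23 members), with 1 and 5 members past the threshold adjusted over the list alone, and under normexp both turned lower, by -0.013 and -0.012. Immediate early genes (0.56), muscle proteolysis (0.31), antioxidant defence, heat shock proteins and endoplasmic reticulum stress genes also lay higher, and the last 3 turned lower under normexp, by -0.054, -0.012 and -0.051. Fast muscle contractile genes lay lower by -0.42 (30 of 34 members, adjusted p = 2.41e-07), as did cholesterol synthesis (-0.25) and cell cycle genes (-0.61). Of the other cell types, markers of epidermis (0.53) and endothelium (0.34) lay higher, and those of bone and cartilage (-0.43) and of neural and glial cells (-0.22) lower. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, passed antioxidant defence (adjusted p = 0.0258). Cell cycle genes turned higher, by 0.63, once the oocyte marker mean was a covariate. With any 1 array of these groups left out, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle, proteasome subunits, muscle proteolysis and immediate early genes kept their calls and moved less than 1.5-fold, and the other 10 lists did not. Without normoxia_control replicate 1, cell cycle (-0.25) and endothelium (0.23) no longer passed. Without normoxia_control replicate 2, endoplasmic reticulum stress (0.21) no longer passed, and cholesterol synthesis (-0.42) moved over 1.5-fold. Without normoxia_control replicate 3, cell cycle (-0.40) and cholesterol synthesis (-0.015) no longer passed. Without normoxia_control replicate 4, heat shock proteins (0.098), endoplasmic reticulum stress (0.17) and antioxidant defence (0.22) no longer passed, and cell cycle (-1.19), neural markers (-0.075) and bone and cartilage markers (-0.29) moved over 1.5-fold. Without normoxia_exercise replicate 1, heat shock proteins (0.23) and endothelium (0.31) no longer passed. Without normoxia_exercise replicate 2, endoplasmic reticulum stress (0.11), antioxidant defence (0.19) and bone and cartilage markers (-0.20) no longer passed, and fast muscle (-0.18), cell cycle (-0.92) and epidermis (0.34) moved over 1.5-fold. Without normoxia_exercise replicate 3, cell cycle (-0.40), heat shock proteins (0.16) and endoplasmic reticulum stress (0.23) no longer passed. Without normoxia_exercise replicate 4, cell cycle (-0.49) and cholesterol synthesis (-0.14) no longer passed.

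The comparison of hypoxia_exercise with normoxia_control asked what swimming under reduced oxygen changes. The gene tnni4a rose by 2.03 ± 0.20 (adjusted p = 0.00122), hbbe3 by 2.99 ± 0.48 (adjusted p = 0.0474), fstl1a by 1.94 ± 0.29 (adjusted p = 0.041) and cox6b1 by 1.89 ± 0.27 (adjusted p = 0.041). The actin regulator gene enah (NM_001045028) rose by 1.93 ± 0.30 (adjusted p = 0.0474), and its probes ranged from 0.57 to 1.93. Their groups again did not overlap, by the naming rule, which also makes each higher on 4 of 4 slides by construction. With zgc:172076, AY329628 and ENSDART00000141278, named after their values were seen, 8 genes rose and 0 fell by limma, and 2852 had an unadjusted p under 0.05. Here too AY329628 ran close to hbbe3 on each array, so they may not be separate signals. Among genes that were lower, none passed, and stra6 (-2.81 ± 0.56, adjusted p = 0.22), spag6, matn3a, nln and col9a1b had the smallest p values. Without normoxia_control replicate 1, 2, 3 or 4 there were 1, 1, 1 and 3 genes, and without hypoxia_exercise replicate 1, 2, 3 or 4 there were 2, 1, 1 and 1. The gene tnni4a passed in all 8 of these fits (largest adjusted p = 0.0103). With slide as a term in the model 1 gene passed, with array quality weights 50 rose and 13 fell, with the authors' values 10 rose and 11 fell, and under normexp or with the oocyte and liver marker means as covariates 0 passed. The adjusted p of tnni4a ranged from 0.000152 to 0.481 over all settings. The oocyte marker mean was lower in hypoxia_exercise by -4.54 (exact permutation p = 0.114).

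Proteasome subunits lay 0.49 higher in hypoxia_exercise than in normoxia_control (42 of 43 members, 4 of 4 slides, adjusted p = 4.66e-11), but lower by -0.064 under normexp. This was 1 of 12 lists of 30 past the threshold by camera with a preset correlation, and none of them held with an estimated correlation (smallest adjusted p = 0.929). Fry, with its own null of no net movement, passed 0 lists (smallest adjusted p = 0.404). Ribosome biogenesis lay 0.25 higher (41 of 50 members, adjusted p = 0.000328), with 5 members past the threshold adjusted over the list alone, among them ddx21 (0.82 ± 0.18) and nop53 (0.81 ± 0.19), and turned lower under normexp, by -0.17. Heat shock proteins and chaperones lay 0.25 higher, with 4 members past the threshold adjusted over the list alone (cct5, cct2, hspa8 and cct3), and immediate early genes (0.37), muscle proteolysis (0.26) and epidermis markers (0.45) were higher too, and these lists turned lower under normexp, by -0.088, -0.026, -0.089 and -0.15. Fast muscle contractile genes (-0.33, 27 of 34 members lower), cholesterol synthesis (-0.32), extracellular matrix (-0.16), cell cycle genes (-0.80), bone and cartilage markers (-0.60) and neural and glial markers (-0.12) lay lower. Leaving out normoxia_control replicate 4 left 7 lists. Cell cycle genes turned higher, by 0.35, with the oocyte marker mean as a covariate. Epidermis and bone and cartilage markers kept their calls and moved less than 1.5-fold with any 1 array of these groups left out, and the other 10 lists did not. Without normoxia_control replicate 1, proteolysis (0.20) and cell cycle (-0.44) no longer passed, and ribosome biogenesis (0.41) and extracellular matrix (-0.26) moved over 1.5-fold. Without normoxia_control replicate 2, extracellular matrix (-0.028) no longer passed, and cholesterol synthesis (-0.49) moved over 1.5-fold. Without normoxia_control replicate 3, cholesterol synthesis (-0.085) no longer passed, and fast muscle (-0.50), extracellular matrix (-0.33) and neural markers (-0.21) moved over 1.5-fold. Without normoxia_control replicate 4, neural markers (0.023) changed sign, proteolysis (0.27), ribosome biogenesis (0.074), heat shock proteins (0.11), immediate early genes (0.38) and extracellular matrix (-0.018) no longer passed, and cell cycle (-1.38) moved over 1.5-fold. Without hypoxia_exercise replicate 1, proteolysis (0.18), cholesterol synthesis (-0.13), extracellular matrix (-0.024) and neural markers (-0.046) no longer passed, and fast muscle (-0.15) and proteasome (0.32) moved over 1.5-fold. Without hypoxia_exercise replicate 2, extracellular matrix (-0.086) and neural markers (-0.046) no longer passed. Without hypoxia_exercise replicate 3, heat shock proteins (0.13) no longer passed, and fast muscle (-0.50), extracellular matrix (-0.37) and neural markers (-0.19) moved over 1.5-fold. Without hypoxia_exercise replicate 4, neural markers (-0.19) moved over 1.5-fold.

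The comparison of hypoxia_low_flow with normoxia_control asked what low oxygen changes with little imposed swimming. Both oxygen (4 against 20 kPa) and imposed flow (7 against 0 cm/s) differed, so their effects cannot be separated in this arm. No gene passed the threshold by limma (0 of 24216, smallest adjusted p = 0.432), and 1942 had an unadjusted p under 0.05. The genes with the smallest p values were vapa (0.86 ± 0.18, adjusted p = 0.432), rasd1, usp2a, aamp and gtpbp4 among those higher, and calr (-0.66 ± 0.12, adjusted p = 0.432, with probes from -0.66 to 0.072), zc3h18, kcnk2b, cxcl11.8 and xylb among those lower. The genes kcnk2b and cxcl11.8 were not above background on any hypoxia_low_flow array and turned higher under normexp, by 0.16 and 0.12. Without hypoxia_low_flow replicate 4, 12 genes rose and 11 fell, but this leaves out the 1 oocyte-rich array of the group. The other arrays of hypoxia_low_flow lay at -2.66 to -2.33 in oocyte markers and 3 of 4 controls at 4.07 to 5.90, so these 23 calls cannot be told from oocyte content and cannot be read as effects of low oxygen. The oxygen sensor gene egln3 was higher by 1.43 ± 0.42 (adjusted p = 0.54), which did not pass. The oocyte marker mean differed by -3.50 (exact permutation p = 0.429).

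Targets of hypoxia-inducible factor lay 0.54 above the other genes in hypoxia_low_flow (29 of 35 members, 4 of 4 slides, adjusted p = 8.73e-05), among them igfbp1b (3.28 ± 0.93), egln3, egln1b and pfkfb4a, and 0 members passed when adjusted over the list alone. This was 1 of 15 lists of 30 past the threshold by camera with a preset correlation, and none of them held with an estimated correlation (smallest adjusted p = 0.554). Fry, with its own null of no net movement, passed 0 lists (smallest adjusted p = 0.238). Immediate early genes lay 0.67 higher (32 of 36 members, adjusted p = 2.51e-06), with dusp1 and cebpd past the threshold adjusted over the list alone, and the circadian clock (0.39), muscle proteolysis (0.35) and glycogen metabolism (0.19) lay higher with 1, 2 and 1 such members. Cytosolic ribosomal proteins (0.17), proteasome subunits (0.21) and ribosome biogenesis (0.16) lay higher but turned lower under normexp, by -0.12, -0.043 and -0.066. Fast muscle contractile genes (-0.30, 29 of 34 members lower), extracellular matrix (-0.35), cell cycle genes (-0.77), oxidative phosphorylation (-0.046) and endoplasmic reticulum stress genes (-0.056) lay lower. Of the other cell types, epidermis markers lay higher by 0.30 and bone and cartilage markers lower by -0.62. Cell cycle genes turned higher, by 0.12, with the oocyte marker mean as a covariate. The circadian clock and bone and cartilage markers kept their calls and moved less than 1.5-fold with any 1 array of these groups left out, and the other 13 lists did not. Without normoxia_control replicate 1, endoplasmic reticulum stress (0.030) changed sign, and ribosome biogenesis (0.31) and cell cycle (-0.41) moved over 1.5-fold. Without normoxia_control replicate 2, glycogen metabolism (0.12), proteasome (0.16) and ribosome biogenesis (0.087) no longer passed, and endoplasmic reticulum stress (-0.098) and extracellular matrix (-0.21) moved over 1.5-fold. Without normoxia_control replicate 3, glycogen metabolism (0.22), cytosolic ribosomal proteins (0.060) and endoplasmic reticulum stress (-0.020) no longer passed, and fast muscle (-0.47) and ribosome biogenesis (0.26) moved over 1.5-fold. Without normoxia_control replicate 4, ribosome biogenesis (-0.021) changed sign, glycogen metabolism (0.16), oxidative phosphorylation (-0.022) and proteasome (0.17) no longer passed, and cell cycle (-1.35), endoplasmic reticulum stress (-0.14) and extracellular matrix (-0.20) moved over 1.5-fold. Without hypoxia_low_flow replicate 1, oxidative phosphorylation (0.018) changed sign, proteasome (0.050) and ribosome biogenesis (0.089) no longer passed, and hypoxia-inducible factor targets (0.35), proteolysis (0.20), endoplasmic reticulum stress (-0.11) and immediate early genes (0.43) moved over 1.5-fold. Without hypoxia_low_flow replicate 2, glycogen metabolism (0.18) and endoplasmic reticulum stress (-0.026) no longer passed, and oxidative phosphorylation (-0.13) moved over 1.5-fold. Without hypoxia_low_flow replicate 3, oxidative phosphorylation (-0.12) and epidermis (0.20) moved over 1.5-fold. Without hypoxia_low_flow replicate 4, oxidative phosphorylation (0.040) changed sign, glycogen metabolism (0.16), ribosome biogenesis (0.13) and endoplasmic reticulum stress (-0.017) no longer passed, and proteasome (0.37), cell cycle (-1.35) and epidermis (0.52) moved over 1.5-fold.

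The comparison of hypoxia_exercise with normoxia_exercise asked how oxygen alters the response to swimming, at speeds that differed by group. No gene passed by limma (0 of 24216), and 367 had an unadjusted p under 0.05, fewer than the 1211 expected on average by chance. The embryonic globin gene hbbe2 (3.07 ± 0.76), pmvk, tert, rgra and cdk15 were the leading higher genes, and nudt8 (-0.51 ± 0.16), cpt2, bola3, hsdl2 and cox7a2a the leading lower ones, each with an adjusted p = 1. The genes pmvk and rgra were above background on 2 and 0 of the normoxia_exercise arrays. Camera with a preset correlation passed 15 lists, and none held with an estimated correlation (smallest adjusted p = 0.164). Fry passed 0 lists (smallest adjusted p = 0.764). Of the lists passed by camera, oxidative phosphorylation lay lower by -0.32 (66 of 68 members, adjusted p = 6.93e-31), fatty acid oxidation by -0.31 (28 of 33 members, 4 of 4 slides, adjusted p = 3.36e-19) and the tricarboxylic acid cycle by -0.26 (20 of 23 members), and 0 members of these lists passed when adjusted over the list alone. Slow muscle contractile genes (-0.20), myogenesis (-0.17), immediate early genes (-0.19), extracellular matrix (-0.16), antioxidant defence (-0.12), cell cycle (-0.19), endoplasmic reticulum stress (-0.11) and epidermis markers (-0.086) also lay lower, and ribosome biogenesis (0.19, 46 of 50 members), erythrocyte markers (0.21), leukocyte markers (0.20) and neural and glial markers (0.098) lay higher. Fatty acid oxidation, the tricarboxylic acid cycle and ribosome biogenesis kept their calls and moved less than 1.5-fold with any 1 array of these groups left out, and the other 12 lists did not. Without normoxia_exercise replicate 1, neural markers (0.043) no longer passed, and endoplasmic reticulum stress (-0.19) moved over 1.5-fold. Without normoxia_exercise replicate 2, cell cycle (0.12), endoplasmic reticulum stress (0.031) and epidermis (0.11) changed sign, antioxidant defence (-0.078), immediate early genes (-0.18) and neural markers (0.029) no longer passed, and myogenesis (-0.28) and extracellular matrix (-0.35) moved over 1.5-fold. Without normoxia_exercise replicate 3, slow muscle (-0.15), myogenesis (-0.14), immediate early genes (-0.13), extracellular matrix (-0.12) and leukocytes (0.14) no longer passed, and cell cycle (-0.40) and epidermis (-0.17) moved over 1.5-fold. Without normoxia_exercise replicate 4, slow muscle (-0.10), myogenesis (-0.11), immediate early genes (-0.16), extracellular matrix (-0.027) and erythrocytes (0.14) no longer passed, and cell cycle (-0.31), endoplasmic reticulum stress (-0.21), epidermis (-0.16) and neural markers (0.18) moved over 1.5-fold. Without hypoxia_exercise replicate 1, slow muscle (-0.088), myogenesis (-0.095), immediate early genes (-0.12) and extracellular matrix (-0.025) no longer passed, and oxidative phosphorylation (-0.20) and neural markers (0.17) moved over 1.5-fold. Without hypoxia_exercise replicate 2, slow muscle (-0.15), myogenesis (-0.15), extracellular matrix (-0.087), erythrocytes (0.13) and leukocytes (0.14) no longer passed, and cell cycle (-0.29), antioxidant defence (-0.19), epidermis (-0.20) and neural markers (0.17) moved over 1.5-fold. Without hypoxia_exercise replicate 3, epidermis (0.024) changed sign, cell cycle (-0.061), endoplasmic reticulum stress (-0.11), immediate early genes (-0.18) and neural markers (0.023) no longer passed, and slow muscle (-0.35), myogenesis (-0.29) and extracellular matrix (-0.37) moved over 1.5-fold. Without hypoxia_exercise replicate 4, endoplasmic reticulum stress (-0.023) and neural markers (0.027) no longer passed, and antioxidant defence (-0.071) moved over 1.5-fold. The liver marker mean differed by 1.3 (exact permutation p = 0.514).

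The comparison of hypoxia_exercise with hypoxia_low_flow placed swimming against low flow, both under reduced oxygen of unequal level. The transcript CN330108, which carries no symbol and was named after its values were seen, rose by 2.40 ± 0.31 (adjusted p = 0.0387) on 4 of 4 slides, so 1 gene rose and 0 fell, and 1286 had an unadjusted p under 0.05. The genes tnni4a (1.23 ± 0.20, adjusted p = 0.253), fstl1a (1.59 ± 0.29), ccnd1, tubb6 and uts2b were higher and dusp1 (-1.32 ± 0.29, adjusted p = 0.434), znf395a, mtus1a, hacl1 and gpib lower, without passing. Camera with a preset correlation passed 8 lists, and none held with an estimated correlation (smallest adjusted p = 0.965). Fry passed 0 lists (smallest adjusted p = 0.978). Proteasome subunits lay 0.28 higher (42 of 43 members, adjusted p = 1.31e-07), and heat shock proteins (0.17), endoplasmic reticulum stress genes (0.19) and interferon response genes (0.27) were higher too, and under normexp these 4 lists turned lower, by -0.021, -0.0014, -0.047 and -0.028. Under normexp 0 lists passed as higher and 17 as lower, against 4 and 4 without it. Targets of hypoxia-inducible factor (-0.23), the circadian clock (-0.30), cholesterol synthesis (-0.42) and neural and glial markers (-0.15) lay lower. No gene passed without hypoxia_exercise replicate 1, 3 or 4 or without hypoxia_low_flow replicate 1, 2 or 4 (0 in each), and 4 passed without hypoxia_low_flow replicate 3. There were 13 lists without hypoxia_exercise replicate 3 and 13 without hypoxia_low_flow replicate 4. Endoplasmic reticulum stress genes alone kept their call and moved less than 1.5-fold with any 1 array of these groups left out. Without hypoxia_exercise replicate 1, hypoxia-inducible factor targets (-0.19), proteasome (0.11), cholesterol synthesis (-0.23), interferon response (0.17) and neural markers (-0.077) no longer passed. Without hypoxia_exercise replicate 2, interferon response (0.045) and neural markers (-0.077) no longer passed. Without hypoxia_exercise replicate 3, heat shock proteins (0.061) no longer passed, and interferon response (0.43) moved over 1.5-fold. Without hypoxia_exercise replicate 4, interferon response (0.43) moved over 1.5-fold. Without hypoxia_low_flow replicate 1, hypoxia-inducible factor targets (-0.036), interferon response (0.41) and neural markers (-0.12) no longer passed, and proteasome (0.44) and circadian clock (-0.19) moved over 1.5-fold. Without hypoxia_low_flow replicate 2, neural markers (-0.084) no longer passed. Without hypoxia_low_flow replicate 3, hypoxia-inducible factor targets (-0.19) and cholesterol synthesis (-0.042) no longer passed. Without hypoxia_low_flow replicate 4, interferon response (-0.053) changed sign, heat shock proteins (0.065) no longer passed, and hypoxia-inducible factor targets (-0.36), proteasome (0.12) and neural markers (-0.24) moved over 1.5-fold. The oocyte marker mean differed by -1.04 (exact permutation p = 0.943).

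The comparison of normoxia_exercise with hypoxia_low_flow set swimming at 20 kPa against low oxygen with low flow, so oxygen and flow both differed. CN330108 rose by 2.41 ± 0.31 (adjusted p = 0.0377), 1 gene rose and 0 fell, and 1612 had an unadjusted p under 0.05. The genes uts2b (2.25 ± 0.34, adjusted p = 0.109), nudt8, tuba1b, fstl1a and nnt were higher and surf2 (-0.68 ± 0.15, adjusted p = 0.274), dio2, lmcd1, egln1b and tcnba lower, without passing. Camera with a preset correlation passed 18 lists, and none held with an estimated correlation (smallest adjusted p = 0.204). Fry passed 0 lists (smallest adjusted p = 0.0644). Fatty acid oxidation lay 0.36 higher (26 of 33 members, adjusted p = 4.79e-11), with 12 members past the threshold adjusted over the list alone, among them acadvl (0.96 ± 0.17) and cpt2 (0.96 ± 0.19). Oxidative phosphorylation lay 0.40 higher (65 of 68 members, adjusted p = 6.17e-19, with 5 such members), and proteasome subunits (0.30), endoplasmic reticulum stress (0.31), extracellular matrix (0.35), the tricarboxylic acid cycle (0.22), antioxidant defence (0.22), interferon response (0.57), cell cycle (0.16) and endothelial markers (0.17) lay higher. Targets of hypoxia-inducible factor (-0.19), fast muscle contractile genes (-0.12), cholesterol synthesis (-0.35), the circadian clock (-0.23), ribosome biogenesis (-0.093), cytosolic ribosomal proteins (-0.043), neural and glial markers (-0.25) and erythrocyte markers (-0.17) lay lower. No gene passed without normoxia_exercise replicate 1, 3 or 4 or without hypoxia_low_flow replicate 1, 2 or 4 (0 in each), 12 passed without normoxia_exercise replicate 2, and 5 without hypoxia_low_flow replicate 3. Oxidative phosphorylation, antioxidant defence and neural and glial markers kept their calls and moved less than 1.5-fold with any 1 array of these groups left out, and the other 15 lists did not. Without normoxia_exercise replicate 1, endothelium (0.13) no longer passed, and cytosolic ribosomal proteins (-0.082) moved over 1.5-fold. Without normoxia_exercise replicate 2, fast muscle (0.13), cytosolic ribosomal proteins (0.011) and cell cycle (-0.15) changed sign, interferon response (0.29) no longer passed, and the tricarboxylic acid cycle (0.33), proteasome (0.17), ribosome biogenesis (-0.14), endoplasmic reticulum stress (0.16), extracellular matrix (0.54) and erythrocytes (-0.26) moved over 1.5-fold. Without normoxia_exercise replicate 3, cytosolic ribosomal proteins (-0.037) and endothelium (0.15) no longer passed, and the tricarboxylic acid cycle (0.15), fast muscle (-0.24), cell cycle (0.37) and interferon response (0.92) moved over 1.5-fold. Without normoxia_exercise replicate 4, hypoxia-inducible factor targets (-0.15), ribosome biogenesis (-0.032), interferon response (0.52), endothelium (0.14) and erythrocytes (-0.10) no longer passed, and fast muscle (-0.19), cytosolic ribosomal proteins (-0.065), cell cycle (0.28), cholesterol synthesis (-0.23) and extracellular matrix (0.21) moved over 1.5-fold. Without hypoxia_low_flow replicate 1, hypoxia-inducible factor targets (0.0027) and cytosolic ribosomal proteins (0.0047) changed sign, ribosome biogenesis (-0.023), cell cycle (0.067), circadian clock (-0.12) and interferon response (0.72) no longer passed, and proteasome (0.45) and endothelium (0.26) moved over 1.5-fold. Without hypoxia_low_flow replicate 2, cell cycle (-0.094) changed sign, fast muscle (-0.061), cytosolic ribosomal proteins (-0.0072), endothelium (0.18) and erythrocytes (-0.11) no longer passed, and hypoxia-inducible factor targets (-0.30) moved over 1.5-fold. Without hypoxia_low_flow replicate 3, cell cycle (-0.073) and cholesterol synthesis (0.028) changed sign, hypoxia-inducible factor targets (-0.15), endothelium (0.18) and erythrocytes (-0.087) no longer passed, and fast muscle (-0.20) and ribosome biogenesis (-0.16) moved over 1.5-fold. Without hypoxia_low_flow replicate 4, fast muscle (-0.063), ribosome biogenesis (-0.063), interferon response (0.25) and endothelium (0.052) no longer passed, and hypoxia-inducible factor targets (-0.32), fatty acid oxidation (0.22), proteasome (0.13), cytosolic ribosomal proteins (-0.13), cell cycle (0.74), circadian clock (-0.35), cholesterol synthesis (-0.54) and erythrocytes (-0.29) moved over 1.5-fold. The oocyte marker mean differed by -1.41 (exact permutation p = 0.657).

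The interaction set the step from hypoxia_low_flow (4 kPa, 7 cm/s) to hypoxia_exercise (6 kPa, 30 cm/s) against the step from normoxia_control (20 kPa, 0 cm/s) to normoxia_exercise (20 kPa, 35 cm/s). Oxygen changed along with speed in the first step, so the interaction does not isolate how oxygen alters the effect of swimming. No gene passed by limma (0 of 24216), and 754 had an unadjusted p under 0.05. The leading positive genes were cxcl11.8, fam117ab (1.54 ± 0.37), nos2b, hao1 and blnk, and the leading negative ones acbd5a (-1.10 ± 0.25), dusp1 (-1.54 ± 0.41), mcl1b, nr1d2a and tbcb, each with an adjusted p = 1, and the smallest adjusted p of any item was 0.737. The gene cxcl11.8 was above background on 0 of 4 hypoxia_low_flow and 1 of 4 normoxia_exercise arrays, so the size of its difference is not known. Immediate early genes gave the largest negative list difference (-0.85, 31 of 36 members, adjusted p = 9.86e-08), with 0 members past the threshold adjusted over the list alone. Camera with a preset correlation passed 15 lists, and none held with an estimated correlation (smallest adjusted p = 0.579). Fry passed 0 lists (smallest adjusted p = 0.56). Cell cycle genes were positive (0.58) and turned negative with the oocyte marker mean as a covariate (-0.40). They no longer passed without normoxia_control replicate 1 (0.22) or hypoxia_low_flow replicate 2 (0.33). Their value fell over 1.5-fold without normoxia_control replicate 3 (0.38), normoxia_exercise replicate 3 (0.37) or hypoxia_low_flow replicate 3 (0.35), and rose over 1.5-fold without normoxia_control replicate 4 (1.16), normoxia_exercise replicate 2 (0.89) or hypoxia_low_flow replicate 4 (1.16). Immediate early genes passed with any 1 array left out. The count of genes was 1 without hypoxia_low_flow replicate 4.

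Of the fixed lists, glycolysis and adipocyte markers passed in none of the 7 tests by camera. Of 17 single genes fixed beforehand, 0 passed in the comparisons with normoxia_control by limma, with smallest adjusted p values for mstnb in hypoxia_exercise (-0.99 ± 0.23, adjusted p = 0.279), for mb (0.95 ± 0.30) in normoxia_exercise (adjusted p = 0.449) and for egln3 in hypoxia_low_flow (adjusted p = 0.54). The fold changes of normoxia_exercise and hypoxia_low_flow, each against normoxia_control, correlated at 0.825 across 24216 genes, which are not independent replicates. In 100 draws, residuals of all arrays were dealt at random into unchanged groups, with a drawn group as the shared reference in place of the controls. Differences from that reference correlated at a median of 0.501 (from -0.635 to 0.943). The draws did not keep the oocyte-rich arrays in the reference, as in the real controls. The covariance was 0.414 against a simulated median of 0.0902 (from -0.0602 to 0.479), a difference of 0.324. Set against separate pairs of controls, in 6 splits, the correlation was 0.231 to 0.614. The comparisons shared 0 called genes, with 0 expected of independent lists, since hypoxia_low_flow had none. The hypoxia_exercise fold changes had a slope of 0.509 on the sum of the other fold changes, with a correlation of 0.906, which is a description only, since all terms share the controls.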

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

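The tests of oocyte and liver transcripts, of wrong labels and of the called genes under a covariate and against hypoxia_low_flow were chosen after those results had been seen. The counts over other splits of the arrays were planned.

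Oocyte transcripts were high on normoxia_control replicates 1 to 3 and on hypoxia_low_flow replicate 4, and the last lay far from its group (gap of 0.964 of the range), as did the milder normoxia_exercise replicate 1 (0.968). These 4 arrays were the 4 highest for 88.6% of oocyte markers, 15 of 44 of which were also above background on all of the 9 lowest arrays. That share restates the pattern and does not test its source, so ovarian tissue in the pools is a candidate source that stays open. The gap within hypoxia_low_flow was 8.74 against at most 4.91 between group means, so group alone does not account for the levels. That gap is itself part of the pattern that was flagged. An exchange of labels between normoxia_control replicate 4 and hypoxia_low_flow replicate 4 cannot be settled. On a scale from its group at 0 to hypoxia_low_flow at 1, the control lay at 0.147 (SE 0.168) over 29 lists, nearer its own group. That SE treats the lists as independent, although all were scored on the same arrays. Over the 50 genes with the smallest p when it was left out, the control lay at 0.737 (SE 0.109), nearer the other group. There its lack of oocyte transcripts may move it away from the other controls, and normoxia_control replicate 3 lay at 0.7. A single wrong label on hypoxia_low_flow replicate 4 cannot be told apart from ovarian content: it lay at 1.09 (SE 0.125) towards the controls over the lists, against -0.399, 0.00337 and 0.364 for the others of its group, and at 1.35 (SE 0.0373) over the 50 genes with the smallest p when it was left out, against 0.196, 0.476 and 0.386, but controls 1 to 3 hold oocyte transcripts too. Single genes on that array do not settle it. The genes egln3 (0.56, controls -1.05 to -0.29) and hbbe2 (0.28, controls -4.85 to -3.38) lay apart from the controls, while vegfaa (0.53) and pfkfb4a (0.31) did not lie above them. However, pfkfb4a did not part the groups on other arrays either, with 0.546 on hypoxia_low_flow replicate 2 and 0.861 on normoxia_control replicate 3.

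Liver transcripts were high on hypoxia_exercise replicate 1 (gap of 0.979 of the range). Of 16 liver markers, 87.5% were highest on this array, with vtg6 at 3.74 and fabp10a at 2.71, which restates the pattern and leaves liver tissue in that pool an open candidate source. Of these markers, 8 were above background on all of the other 15 arrays and the most abundant, rbp4, was at 7.93 there and 7.57 to 8.40 elsewhere. The gap to the nearest of the group was 5.16 against at most 1.3 between group means. A lone high array in a group of 4 gives that order by itself. It therefore restates that the rest of the group did not share the high level, which group alone does not account for. No biological explanation was tested.

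The genes that rose in the exercise groups against control were set against oocyte transcripts on the control arrays. With the oocyte marker mean as a covariate the called genes kept a median of 95.3% of their log2 fold change (lower quartile 85.2%). For these genes that argues against oocyte transcripts as the whole cause, but only weakly. They were picked on the same arrays, where a small spread within groups favours a call, so part of this share may be kept by selection. The calls nevertheless ended except for tnni4a in hypoxia_exercise (2.03 ± 0.20 before, 1.98 ± 0.24 after, adjusted p = 0.0199), some mainly with a larger error, as for tnni4a (1.81 ± 0.20 to 1.75 ± 0.24, adjusted p = 0.104) and cox6b1 (1.90 ± 0.27 to 1.87 ± 0.33) in normoxia_exercise, and some mainly with a smaller fold change, as for fstl1a there (2.00 ± 0.29 to 1.65 ± 0.30). Against hypoxia_low_flow, a comparison without control arrays, the called genes kept a median of 70.6% of their fold change (lower quartile 62.9%, from 39.3% to 82.3%). Counted in each exercise group, with the closely matching hbbe3 and AY329628 as separate genes, all 15 differences exceeded 2 standard errors. Of these, 13 of 15 were without overlap of the groups, the others being enah and ENSDART00000141278 in hypoxia_exercise. This argues against a difference of the control pools as the whole cause, although it may hold a part, and although these genes were picked on the same exercise arrays and none of them passed the adjustment over all genes against hypoxia_low_flow (smallest adjusted p = 0.129). Swimming, which the design names, stays among the open explanations. Oxygen was the same in normoxia_exercise and normoxia_control, so there swimming was set apart from oxygen by design, but not from imposed flow. In hypoxia_exercise against normoxia_control, and in the comparisons with hypoxia_low_flow, swimming was not tested apart from oxygen and flow. The range of adjusted p for tnni4a over all alternatives was 0.000319 to 0.388 in normoxia_exercise and 0.000152 to 0.481 in hypoxia_exercise, with both low ends from a subset of 14 arrays in which oocyte content follows the groups.

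In counts of genes, the real split stood alone for normoxia_exercise against normoxia_control (1 of 35 splits gave as many, with 7 genes against at most 1 in another split). It also stood alone for hypoxia_exercise against normoxia_control (1 of 35, with 8 against at most 1). A share of 1 of 35 is the smallest these splits allow. Both comparisons use the same controls, and no allowance was made for the number of comparisons, so chance is not excluded there. Nor is it for hypoxia_exercise against hypoxia_low_flow (3 of 35, real 1, highest other 2) or normoxia_exercise against hypoxia_low_flow (2 of 35, real 1, highest other 1). Where the real count was 0, every split gives as many by construction and the share says nothing about chance: this holds for hypoxia_low_flow against normoxia_control (35 of 35, highest other 3896), hypoxia_exercise against normoxia_exercise (35 of 35, highest other 4) and the interaction (100 of 100 splits drawn, highest other 506). The split with 3896 genes exchanged normoxia_control replicate 4 and hypoxia_low_flow replicate 4, that is, it parted the arrays by oocyte content, which points to a structure of the samples. In counts of lists, chance could not be excluded in any comparison: as many were given by 7 of 35 splits for hypoxia_low_flow against normoxia_control (real 15, highest other 17), 5 for normoxia_exercise against normoxia_control (16 and 19), 19 for hypoxia_exercise against normoxia_control (12 and 21), 15 for hypoxia_exercise against normoxia_exercise (15 and 22), 32 for hypoxia_exercise against hypoxia_low_flow (8 and 20), 2 for normoxia_exercise against hypoxia_low_flow (18 and 18), and 25 of 100 for the interaction (15 and 21).

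Single arrays far from the rest of their group, by the gap over the group's range, were found in 28 of 292 groups tested, where chance gives about 1 in 20. For normoxia_control, replicate 3 was low in glycolysis (0.881), fast muscle genes (0.859) and enah (0.862) and high in proteasome subunits (0.901), replicate 4 was high in the tricarboxylic acid cycle (0.833), slow muscle genes (0.858) and erythrocyte markers (0.832), and replicate 1 was low in the circadian clock (0.887) and fstl1a (0.869). In normoxia_exercise, replicate 2 was low in glycolysis (0.868), oxidative phosphorylation (0.927), fast muscle genes (0.919), fstl1a (0.832), tert (0.934), nnt (0.844) and ENSDART00000136543 (0.83), and replicate 3 was low in cdk15 (0.832). In hypoxia_low_flow, replicate 4 was high in cell cycle genes (0.832) and adipocyte markers (0.941) and low in heat shock proteins (0.983), interferon response genes (0.849) and uts2b (0.861), and replicate 3 was low in bone and cartilage markers (0.894). In hypoxia_exercise, replicate 4 was high in znf395a (0.937) and replicate 3 low in nos2b (0.913).

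In camera with a preset correlation, 15 lists passed the interaction, which sets the step from hypoxia_low_flow (4 kPa, 7 cm/s) to hypoxia_exercise (6 kPa, 30 cm/s) against the step from normoxia_control (20 kPa, 0 cm/s) to normoxia_exercise (20 kPa, 35 cm/s). Oxygen and speed both changed in the first step, so this is not an effect of swimming compared between oxygen levels. None of the lists held with an estimated correlation, and chance is not excluded, since 25 of 100 splits gave as many. The interaction value was negative for targets of hypoxia-inducible factor (-0.58), the tricarboxylic acid cycle (-0.32), oxidative phosphorylation (-0.28), fatty acid oxidation (-0.46), mitochondrial biogenesis regulators (-0.28), muscle proteolysis (-0.39), proteasome subunits (-0.22), cytosolic ribosomal proteins (-0.17), the circadian clock (-0.46), immediate early genes (-0.85) and epidermis markers (-0.38). It was positive for fast muscle genes (0.39), cell cycle genes (0.58, but -0.40 with the oocyte covariate, -0.33 with both covariates and -0.59 with 12 arrays), extracellular matrix (0.19) and bone and cartilage markers (0.45). With any 1 array left out, the tricarboxylic acid cycle, fatty acid oxidation, the circadian clock and immediate early genes kept their calls and moved less than 1.5-fold. Without normoxia_control replicate 1, cell cycle (0.22) no longer passed, and extracellular matrix (0.29) moved over 1.5-fold. Without normoxia_control replicate 2, mitochondrial biogenesis (-0.24), proteasome (-0.17) and extracellular matrix (0.053) no longer passed. Without normoxia_control replicate 3, cytosolic ribosomal proteins (-0.062) no longer passed, and cell cycle (0.38) and extracellular matrix (0.36) moved over 1.5-fold. Without normoxia_control replicate 4, mitochondrial biogenesis (-0.33), proteasome (-0.18) and extracellular matrix (0.043) no longer passed, and cell cycle (1.16) moved over 1.5-fold. Without normoxia_exercise replicate 1, mitochondrial biogenesis (-0.29) and cytosolic ribosomal proteins (-0.13) no longer passed, and proteasome (-0.33) moved over 1.5-fold. Without normoxia_exercise replicate 2, extracellular matrix (-0.0032) changed sign, fast muscle (0.15), proteasome (-0.092) and bone and cartilage markers (0.22) no longer passed, and cell cycle (0.89) and epidermis (-0.19) moved over 1.5-fold. Without normoxia_exercise replicate 3, mitochondrial biogenesis (-0.20) and proteasome (-0.16) no longer passed, and cell cycle (0.37) moved over 1.5-fold. Without normoxia_exercise replicate 4, cytosolic ribosomal proteins (-0.15) no longer passed, and extracellular matrix (0.32) moved over 1.5-fold. Without hypoxia_exercise replicate 1, oxidative phosphorylation (-0.16), mitochondrial biogenesis (-0.23) and cytosolic ribosomal proteins (-0.10) no longer passed, and proteasome (-0.39) and extracellular matrix (0.32) moved over 1.5-fold. Without hypoxia_exercise replicate 2, mitochondrial biogenesis (-0.25) and cytosolic ribosomal proteins (-0.13) no longer passed. Without hypoxia_exercise replicate 3, extracellular matrix (-0.024) changed sign, fast muscle (0.22), proteasome (-0.14) and bone and cartilage markers (0.21) no longer passed, and oxidative phosphorylation (-0.42) moved over 1.5-fold. Without hypoxia_exercise replicate 4, proteasome (-0.083) no longer passed. Without hypoxia_low_flow replicate 1, mitochondrial biogenesis (-0.24), proteasome (-0.066) and cytosolic ribosomal proteins (-0.12) no longer passed, and hypoxia-inducible factor targets (-0.38), proteolysis (-0.24) and extracellular matrix (0.29) moved over 1.5-fold. Without hypoxia_low_flow replicate 2, mitochondrial biogenesis (-0.22), cytosolic ribosomal proteins (-0.13), cell cycle (0.33) and extracellular matrix (0.19) no longer passed. Without hypoxia_low_flow replicate 3, extracellular matrix (0.11) no longer passed, and cell cycle (0.35) moved over 1.5-fold. Without hypoxia_low_flow replicate 4, extracellular matrix (0.15) no longer passed, and proteasome (-0.39), cell cycle (1.16) and epidermis (-0.60) moved over 1.5-fold.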

How the results depend on the processing

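Normexp on the median signal, the oocyte and liver covariates and the subsets of 12 and 14 arrays were chosen after the data were seen. The planned normexp on the mean signal was not run. Of the named genes' values under other settings, 1657 kept their direction and side of the threshold, 212 no longer passed, 36 newly passed and 3 reversed. Of the list values, 2094 stayed, 324 no longer passed and 63 reversed. Unless a reason is given, the cause was not tested.

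For normoxia_exercise against normoxia_control, 7 genes became 0 under normexp, 12 with the authors' values (7 shared, 10 higher and 2 lower), 5 with slide as a block, 58 with array quality weights (7 shared, 41 higher and 17 lower), 0 with the oocyte covariate and 0 with oocyte and liver covariates. Without single arrays the count was 1 (without normoxia_control replicate 2, among others) to 10 (without normoxia_control replicate 3). For hypoxia_exercise against normoxia_control, 8 genes became 0 under normexp, 21 with the authors' values (8 shared), 4 without the filter, 4 with the mean of probes, 1 with slide as a block, 1 without variance trend, 63 with weights (8 shared, 50 higher and 13 lower), 1 with the oocyte covariate and 0 with both covariates, and 1 to 3 without single arrays. The split of higher and lower calls, 8 and 0, became 10 and 11 with the authors' values. With 12 arrays, which leave out the 4 highest in oocyte transcripts and so were picked by a measured value, these comparisons gave 9 and 11 genes (9 higher and 0 lower, 8 higher and 3 lower), 0 of them shared with the main lists, from a lone control assumed to vary like the other groups.

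For hypoxia_low_flow against normoxia_control, 0 genes became 1 with the authors' values, 8 with 12 arrays, and 0 to 23 without single arrays (23 without hypoxia_low_flow replicate 4, which lines oocyte content up with the control group, so that these calls cannot be read as effects of low oxygen). For hypoxia_exercise against hypoxia_low_flow, 1 gene became 0 under normexp, quantile normalisation, no filter, the oocyte covariate, both covariates, 14 arrays and 12 arrays, 2 with the authors' values (0 shared, both lower), and 0 to 4 without single arrays. For normoxia_exercise against hypoxia_low_flow, 1 gene became 0 under normexp, quantile normalisation, no filter, only the groups compared, both covariates, 14 arrays and 12 arrays, 6 with the authors' values (0 shared, 4 higher and 2 lower), 32 with weights (1 shared, 28 higher and 4 lower), 2 with the oocyte covariate (1 higher and 1 lower), and 0 to 12 without single arrays. For the interaction, 0 became 1 with the authors' values, 2 with 12 arrays, and 0 to 1 without single arrays. For hypoxia_exercise against normoxia_exercise the count was 0 in every alternative run.

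The subset of 14 arrays left out normoxia_control replicate 4 and hypoxia_low_flow replicate 4 and was tried while the data were being looked at. It gave 2323 genes for hypoxia_low_flow (1044 higher), 1095 for normoxia_exercise (225 higher) and 1341 for hypoxia_exercise (398 higher) against normoxia_control, and 674 for the interaction (599 positive). By construction it lines oocyte content up with the control group, so these counts cannot be read as effects of oxygen or swimming.

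No pairing by replicate number was seen: 9 of 24 same-numbered pairs had residuals correlated above 0.1 (from -0.746 to 0.39). Of differently numbered pairs 24 of 72 did (from -0.483 to 0.643), and 5 of 16 arrays correlated best with their own number. The lowest value, -0.746, joined normoxia_control replicate 4 and hypoxia_low_flow replicate 4, which differ in oocyte content. Such content moves these residuals, so a pairing is not excluded. With the replicate number as a block, hypoxia_exercise against normoxia_control gave 1 gene and normoxia_exercise against normoxia_control 9, and no other count of genes changed.

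Past the threshold by camera were 12 lists for hypoxia_exercise against normoxia_control, 7 with 14 arrays and 7 to 15 without single arrays, and 8 for hypoxia_exercise against hypoxia_low_flow, 17 under normexp (4 shared), 14 with weights (6 shared, 5 higher and 9 lower) and 7 to 13 without single arrays. Normexp changed the split of higher and lower lists from 4 and 4 to 0 and 17 there. It also did so in hypoxia_exercise (6 and 6 to 0 and 14), normoxia_exercise (11 and 5 to 3 and 11) and hypoxia_low_flow (9 and 6 to 3 and 8) against normoxia_control, and in hypoxia_exercise against normoxia_exercise (4 and 11 to 2 and 18). The correlation of 0.825 between exercise and hypoxia responses became 0.514 with the authors' values, 0.552 with the oocyte covariate, 0.557 with both covariates and 0.481 as the median with split controls. The additivity slope of 0.509 became 0.624 with the authors' values.

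Normexp moved the median of all genes by up to 0.259, the 12-array subset by 0.181, the 14-array subset by 0.126 and the covariates by 0.102 and 0.103, and list values are relative to the other genes. Under normexp these lists reversed. Against normoxia_control in hypoxia_low_flow they were proteasome (-0.043), cytosolic ribosomal proteins (-0.12) and ribosome biogenesis (-0.066). In normoxia_exercise they were the tricarboxylic acid cycle (-0.012), oxidative phosphorylation (-0.013), heat shock (-0.012), endoplasmic reticulum stress (-0.051) and antioxidant defence (-0.054). In hypoxia_exercise they were proteolysis (-0.089), proteasome (-0.064), ribosome biogenesis (-0.17), heat shock (-0.088), immediate early genes (-0.026) and epidermis (-0.15). In hypoxia_exercise against hypoxia_low_flow they were proteasome (-0.021), heat shock (-0.0014), endoplasmic reticulum stress (-0.047) and interferon (-0.028). The genes kcnk2b (0.16) and cxcl11.8 (0.12) in hypoxia_low_flow and chrna11 (0.071) in normoxia_exercise reversed too.

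Cell cycle genes reversed with the oocyte covariate, both covariates and 12 arrays: 0.12, 0.11 and 0.40 in hypoxia_low_flow, 0.63, 0.62 and 1.15 in normoxia_exercise, 0.35, 0.41 and 0.96 in hypoxia_exercise against control, and -0.40, -0.33 and -0.59 in the interaction. With 12 arrays, endoplasmic reticulum stress in hypoxia_low_flow (0.22), cholesterol synthesis in normoxia_exercise (0.028) and interferon in hypoxia_exercise against hypoxia_low_flow (-0.053) reversed. With 14 arrays, oxidative phosphorylation (0.063) and ribosome biogenesis (-0.051) in hypoxia_low_flow, neural markers in hypoxia_exercise (0.023) and interferon in hypoxia_exercise against hypoxia_low_flow (-0.053) reversed. With weights, oxidative phosphorylation in hypoxia_low_flow (0.095), cell cycle (0.081), endoplasmic reticulum stress (0.0073), epidermis (0.12) and neural markers (-0.020) in hypoxia_exercise against normoxia_exercise, and fast muscle in normoxia_exercise against hypoxia_low_flow (0.015) reversed.

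Without single arrays, list values that reversed ranged as follows. In hypoxia_low_flow against control they were -0.13 to 0.040 for oxidative phosphorylation, -0.021 to 0.31 for ribosome biogenesis and -0.14 to 0.030 for endoplasmic reticulum stress, and in hypoxia_exercise against control -0.21 to 0.023 for neural markers. In hypoxia_exercise against normoxia_exercise they were -0.40 to 0.12 for cell cycle, -0.21 to 0.031 for endoplasmic reticulum stress and -0.20 to 0.11 for epidermis, and against hypoxia_low_flow -0.053 to 0.43 for interferon. In normoxia_exercise against hypoxia_low_flow they were -0.32 to 0.0027 for targets of hypoxia-inducible factor, -0.24 to 0.13 for fast muscle, -0.13 to 0.011 for cytosolic ribosomal proteins, -0.15 to 0.74 for cell cycle and -0.54 to 0.028 for cholesterol synthesis. In the interaction the range was -0.024 to 0.36 for extracellular matrix. Signal over background limits genes such as kcnk2b and cxcl11.8, which were not above background on any hypoxia_low_flow array (0 of 4).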

Other observations

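The mean of 18 testis markers was 0.42 ± 0.49 (SD, n = 4) in normoxia_control, -0.25 ± 0.25 in normoxia_exercise, -0.23 ± 0.11 in hypoxia_exercise and 0.057 ± 0.63 in hypoxia_low_flow. The smallest exact permutation p among its 6 comparisons was 0.0571 (adjusted p = 0.457), where 0.0286 is the smallest p the design allows. The mean of 15 kidney markers was 0.26 ± 0.39 in normoxia_control, -0.25 ± 0.55 in normoxia_exercise, 0.052 ± 0.40 in hypoxia_exercise and -0.064 ± 0.48 in hypoxia_low_flow, with a smallest exact permutation p of 0.2 (adjusted p = 0.771). These lists were written after the data had been seen.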
